A study of Mus musculus with 4 samples.

How the data were processed

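Gene expression was measured in lymphoid-primed multipotent progenitors (LMPPs) from mouse bone marrow, early blood progenitors with reduced erythroid and megakaryocytic potential. Per the labels, the cells were sorted without lineage markers, with Kit and Sca-1 and with high Flt3, from wild-type and Lyl1-null C57Bl/6 mice of 6 to 8 weeks. RNA was amplified, biotin-labelled and hybridised to a 3' expression array of short probes. There were 4 libraries, 2 per genotype, each on its own array. The number of arrays limits the precision of every value. The labels do not say whether the libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

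The deposited values are log2 expression values made with RMA, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each probe set. Its version, and whether these arrays were normalized alone or with others, are not given in the sources used here. The deposited columns had medians of 5.65 and 5.65 in the wild-type libraries and 5.68 and 5.76 in the libraries labelled Lyl1-null replicate 1 and replicate 2. Their SDs over probe sets were 2.48, 2.47, 2.44 and 2.34 in that order. The values were used as deposited, without another normalization.

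Of 45037 probe sets, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 were not listed with a gene. The gene identifiers of 34741 probe sets matched a table of mouse RefSeq genes, and 0 symbols changed. That table, of assembly GRCm38.p6, was used for names and for the order of neighbouring genes. No coordinates are given, since no build is named for the array. Each gene was read from the probe set with the highest mean over the 4 libraries. Genes were tested where that mean reached the median of all probe-set means, a log2 value of 5.69. This left 11196 of 18193 genes. Probe sets with several genes or none were left out of the gene tests, and no array control probe sets were analysed here, so the planned check of RNA integrity was not made.

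Libraries labelled Lyl1-null were compared with wild-type libraries in limma 3.58.1 under R 4.3.3, with lmFit and eBayes, two-sided tests and Benjamini-Hochberg adjustment at 0.05. All adjusted p-values of genes come from this tool. Differences are Lyl1-null minus wild type on the log2 scale, with the standard error (SE) from the moderated variance. Gene lists were tested with camera, which compares a list's genes with all other genes tested, at a preset inter-gene correlation of 0.01 and with adjustment over 22 lists. Camera was repeated with an estimated correlation, and with fry, which tests a list's genes on their own. With an estimated correlation, camera takes its degrees of freedom from the residuals, 2 with all libraries. Passing over 22 lists is then unlikely even without correlation between genes, so a failure in that setting alone says little about a list. Where the estimated correlation lay above the preset one, the p at the preset correlation may itself be too small. The lists covered the transcription factor complex of Lyl1, blood lineages, other cell types the gate could hold, cell cycle, metabolism, handling stress, interferon response, receptors and the 25 neighbours of Lyl1 on each side. Sex-linked genes were read per library, without a list test.

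The lists, the tests and the rule for the genes to be named were fixed before the data were examined. The rule took Lyl1, then the 10 genes with the largest difference in each direction among those past the threshold with 1 sign in all 4 Lyl1-null against wild-type pairs, filled up to 10 by the smallest unadjusted p. It also took up to 4 members of each list past the threshold, or otherwise the 2 with the smallest p, and named genes that passed adjusted over a list alone as such. Gfi1, Il7r, Notch1, Flt3, Kit, Ly6a, Tal1, Lmo2, Gata2, Gata3, Rag1, Dntt, Tcf3 and Ikzf1 were always taken. RIKEN clones and predicted genes were skipped as names. Ly6a was not analysed here, as no probe set listed it as its single gene.

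Alternatives were the filter (none, or the 70th percentile), all probe sets or their mean per gene, quantile normalization, median centring, a trended or robust prior, array weights, a threshold of 0.10, the replicate number as a block, and each library left out in turn. A fit without 1 library leaves a single library in its group, which is then assumed to vary like the other group. A crossed block, which pairs replicate 1 of each group with replicate 2 of the other, and the list of the Lyl1 complex without Lyl1 were added after the data had been seen. The gene test was tested on simulated data with known changes in 200 of 11196 genes, in 20 runs, with gene variances drawn from the fitted prior. With 2 libraries per group it recovered 12.2% of the 2-fold changes, 88.4% of the 4-fold, 97.4% of the 8-fold and 98.7% of the 16-fold changes, and 4.78% of its calls were false. With 1 Lyl1-null library left out it recovered 1.10%, 66.3%, 93.9% and 97.8%, with 7.27% false calls. Camera, for the same comparison and genes at an unadjusted p under 0.05, called 20 of 20 simulated lists of 40 genes shifted by 0.5 (log2). It called 0 of 20 unshifted lists. All simulated errors were independent between genes and equally wide in the 4 libraries. Real lists had estimated correlations of up to 0.667 (ribosomal proteins), and the library labelled Lyl1-null replicate 2 deviated more than the others. The 200 planted changes also make the adjusted threshold easier to reach. These rates need not hold for the real data. Figures were drawn with matplotlib 3.10.9.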

Results

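The data comprised 4 expression arrays of sorted LMPPs, 2 from wild-type mice and 2 from mice labelled Lyl1-null. Lyl1 is a basic helix-loop-helix transcription factor of blood progenitors, a close relative of Tal1. The design asks which genes of this early lymphoid-primed population depend on it. Values are log2 RMA expression values, and each group had n = 2.

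Lyl1 itself was read first, from its 1 probe set on the array (1419120_at). It stood at 12.34 and 12.29 in the wild-type libraries and at 5.14, below the expression filter of 5.69, in the library labelled Lyl1-null replicate 1. The library labelled Lyl1-null replicate 2 read 10.32, which is 25.1% of the wild-type mean and goes against its label. Xist, the RNA that silences an X chromosome in females, was at 14.26 in that library and between 5.81 and 6.30 in the other 3. The Y-linked gene Eif2s3y was at 8.44 there and between 10.07 and 10.15 in the others, so that library differed from the rest in sex-linked transcripts too. With all 4 libraries, the Lyl1 difference was −4.58 (SE 1.57, adjusted p = 0.644) and did not pass. Lyl1 fell by 7.17 on the log2 scale without the library labelled Lyl1-null replicate 2 (adjusted p = 2.88e-05) and by 1.99 without the library labelled replicate 1 (adjusted p = 0.00471). Background signal compresses the first of these differences, since 5.14 lies below the filter. Over 16 alternatives its adjusted p ranged from 2.88e-05 to 0.9999. The part of Lyl1 that the allele removes, relative to this probe set, is not given in the sources used here.

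**Figure D1:**
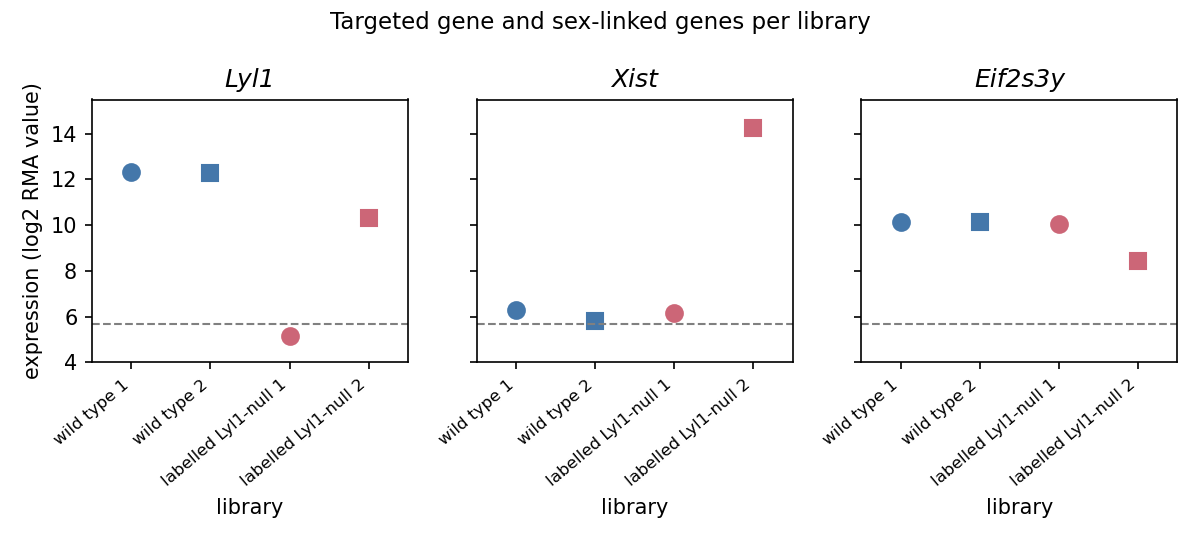
Log2 RMA value (vertical axis) of Lyl1, Xist and Eif2s3y in each of the 4 libraries (horizontal axis), with blue points for wild type, red for the libraries labelled Lyl1-null, circles for replicate 1, squares for replicate 2 and a dashed line at the expression filter of 5.69. The library labelled Lyl1-null replicate 2 reads 10.32 for Lyl1, 14.26 for Xist and 8.44 for Eif2s3y.

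Ctse, which encodes the aspartic protease cathepsin E, was the 1 gene of 11196 that passed the test. It fell from 11.38 ± 0.08 in wild type to 7.37 ± 0.21 in the libraries labelled Lyl1-null (SD, n = 2 each), a difference of −4.02 (SE 0.18, adjusted p = 0.0145) or 16.2-fold. It was lower by a similar amount in both, −4.16 in the library labelled replicate 1 and −3.87 in the one labelled replicate 2. Just outside the threshold lay Cxcr4, the receptor for the marrow-retention chemokine Cxcl12, with a difference of −2.70 (SE 0.18). Nav1, a microtubule-associated protein, had a difference of 2.47 (SE 0.18) and Lrmda one of 3.54 (SE 0.26), each of these 3 at an adjusted p of 0.0513. The chromatin factor Hmga2, known from fetal stem cells, had −2.62 (SE 0.23) and Ankrd6 had −2.39 (SE 0.21), both at an adjusted p of 0.0976. At an unadjusted p under 0.05 there were 766 genes, 243 with a positive and 523 with a negative difference, where 560 would come from chance. A second Ctse probe set (1427797_s_at) was dim, at 4.81 in wild type, and with the mean of probe sets Ctse no longer passed (−2.19, adjusted p = 0.111). Its adjusted p ranged from 5.76e-04 to 0.111 over 16 alternatives, and 15 of them kept the call.

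Of the other genes among the 10 with the smallest p in each direction, none passed over all genes. Positive differences were read for the neutrophil granule gene Ngp (1.997), Tfcp2l1 (1.79), the receptor phosphatase Ptprf (1.75), the calcium-binding S100a8 (1.64), the phosphodiesterase Pde2a (1.61), the T-cell surface protein Thy1 (1.30), Plekha7 (1.22) and Tnni1 (1.17). Negative differences were read for the adhesion molecule Chl1 (−2.01), the lymphocyte GTPase Gimap8 (−1.79), Mamdc2 (−1.74), Tent5a (−1.61), Gadd45gip1 (−1.57) and the ganglioside synthase St8sia1 (−1.36). Hmga2 had 4 probe sets, with differences of −2.62, −2.59, −2.47 and −2.30. Nav1 had 4 as well, from 0.70 to 2.47. Other probe sets above the filter read 0.76 and 0.66 for Pde2a and 2.53 for Ptprf. The other Gadd45gip1 probe set, below the filter, went the opposite way (0.50). Over all tested genes, 103 differed at least 2-fold with no overlap between the groups, 35 positive and 68 negative. Without a limit on size, chance alone separates the groups in 33.3% of genes, so that share is no baseline for the 103.

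**Figure D2:**
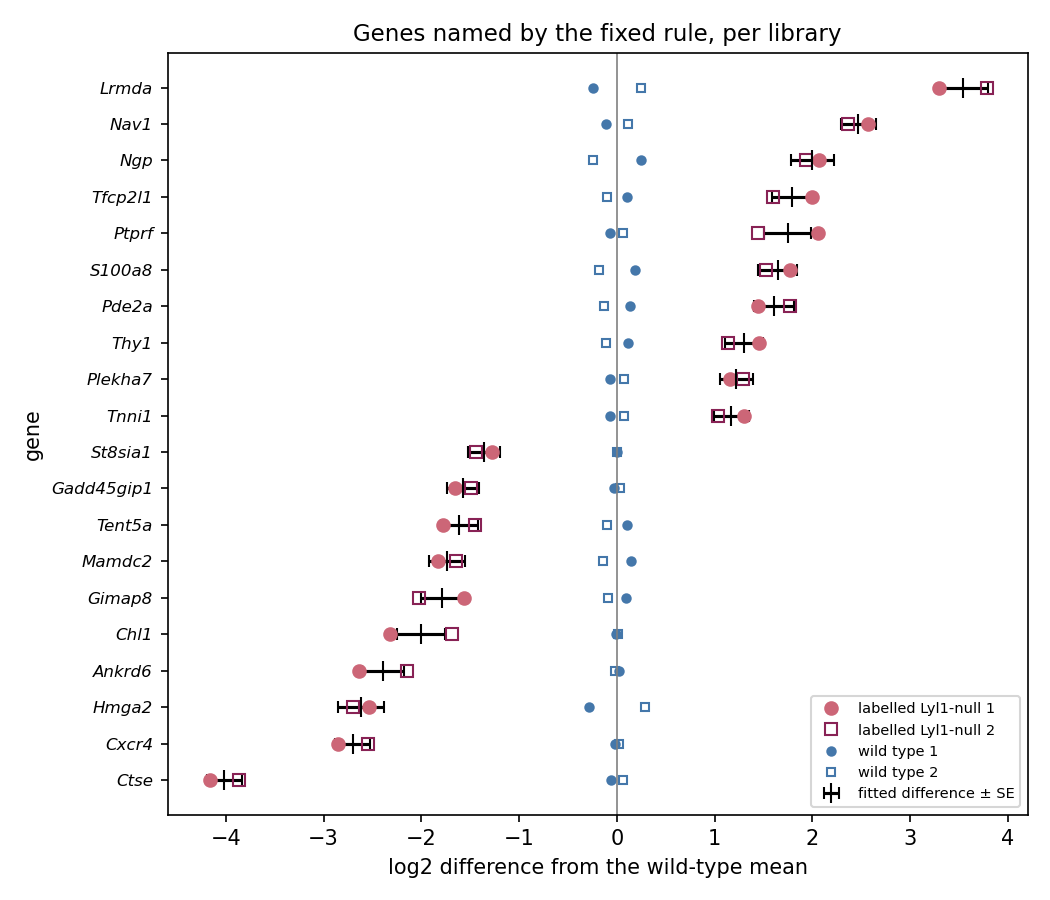
Log2 difference from the wild-type mean (horizontal axis) for the 20 genes of the naming rule (vertical axis), with black bars for the fitted difference ± SE, red and open purple symbols for the libraries labelled Lyl1-null replicate 1 and 2, and blue symbols for wild type. The fitted differences run from Ctse at −4.02 to Lrmda at 3.54, and the choice by smallest p favours genes on which both libraries labelled Lyl1-null agree.

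The count of genes rested on which libraries entered. Without the library labelled Lyl1-null replicate 2, 22 genes passed, with Lyl1, Ctse, Cxcr4, Ankrd6, Chl1, Hmga2, Gadd45gip1, Tent5a, Mamdc2, Fxyd1, Gimap8 and Slc16a11 lower and Nav1, Lrmda, Ptprf, Sbspon, Tfcp2l1, Ltf, Ngp, Cdkn1a, S100a8 and Klhl30 higher. The library left out had the same sign for all 22. Without the library labelled Lyl1-null replicate 1, 1652 genes passed, 441 higher and 1211 lower, and without wild-type replicate 2 there were 2, Ctse and Lrmda. Of the 22 genes, 21 were also among the 1652 in the same direction, 9 higher and 12 lower, with Klhl30 the exception. Independent lists of these sizes would share 0.394 higher and 1.30 lower genes. In 100 simulations of unchanged groups against shared controls, the mean shared was 0.110 and the most 4. Unchanged groups yield few calls to share, so these simulations cannot gauge the overlap between lists of these sizes. Part of the sharing above that of independent lists may come from the shared wild-type libraries, which were too few to split. The library labelled Lyl1-null replicate 2 also stood apart overall: 518 to 859 genes differed at least 2-fold between it and each other library, against 42 to 128 between the other 3.

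Receptors and adhesion molecules of progenitors tended to be lower in the libraries labelled Lyl1-null, mostly in the one labelled replicate 2. Of 45 tested members, 33 had a negative difference, the median was −0.24 and the list passed camera at the preset correlation (adjusted p = 0.0161). It did not pass with an estimated correlation (adjusted p = 0.758) or with fry (0.426). Its estimated correlation, 0.115, was above the preset one of 0.01, so the p at the preset correlation may be too small. The median was −0.084 in the library labelled replicate 1 and −0.39 in the one labelled replicate 2. The lymphoid priming list, which did not pass camera, had medians of −0.080 and −0.35 in these libraries. None of the receptor and adhesion genes passed over all genes, and 3 passed adjusted over their list alone. These were Cxcr4 (−2.70), the SLAM family protein Cd48 (−1.03) and Csf2rb (−1.06), the shared chain of the GM-CSF, IL-3 and IL-5 receptors. A second Csf2rb probe set above the filter read −0.25. Kit, the stem cell factor receptor and a sorting marker, read −0.90 (adjusted p = 0.644). It was at −0.61 in the library labelled Lyl1-null replicate 1 and at −1.20 in the one labelled replicate 2. The sorting marker Flt3 read −0.49 (adjusted p = 0.644) and the interleukin-7 receptor Il7r 0.65 (adjusted p = 0.644). A second Il7r probe set above the filter read 0.27, and −0.17 in the library labelled Lyl1-null replicate 2. Flt3 read −0.22 without the library labelled Lyl1-null replicate 2 and passed without the one labelled replicate 1 (−0.76, adjusted p = 0.0381). Without the library labelled Lyl1-null replicate 1 the list did not pass (adjusted p = 0.0716). Its adjusted p ranged from 7.08e-04 to 0.758 over 14 alternatives, all in the same direction. Beside this group, the neutrophil granule gene Ngp read 1.997 and the granule gene Mpo −1.01.

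Interferon response genes were lower as a group, with 33 of 42 negative, a median of −0.15 and a camera adjusted p of 0.0419 at the preset correlation. The list did not pass with an estimated correlation (adjusted p = 0.758) or with fry (0.277). Its estimated correlation, 0.0042, was below the preset one, yet camera's p rose from 0.00381 to 0.0866. The failure in that setting thus reflects fewer degrees of freedom rather than correlation. The immunity GTPase Iigp1 (−1.28) passed adjusted over the list alone, 0 members passed over all genes, and Ifit1 read −0.62 (adjusted p = 0.644). The list also failed without the library labelled Lyl1-null replicate 1 (adjusted p = 0.346), without wild-type replicate 2 (0.122), with the stricter filter (0.152) and with a block that pairs unlike replicate numbers (0.0502), within a range of 7.62e-06 to 0.758 over 14 alternatives. Ngp read 1.997 beside this group as well.

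Early T-lineage and Notch genes were higher as a group, with 14 of 19 positive, a median of 0.14 and a camera adjusted p of 0.0471 at the preset correlation. The list did not pass with an estimated correlation (adjusted p = 0.758) or with fry (0.238). Its estimated correlation, 0.023, was above the preset one. The median was 0.10 in the library labelled Lyl1-null replicate 1 and 0.30 in the one labelled replicate 2. Thy1 (1.30), a surface protein of T cells, passed adjusted over the list alone and 0 members passed over all genes. Notch1, the receptor that drives T-cell commitment, read −0.53 (adjusted p = 0.644), against the direction of the list, and Gata3 lay below the filter in every library (4.60 and 4.37 in wild type, 4.90 and 4.79 in the libraries labelled Lyl1-null). The list failed without the library labelled Lyl1-null replicate 1 (adjusted p = 0.117), without the library labelled replicate 2 (0.0581), without wild-type replicate 1 (0.0599), with quantile normalization (0.111), with the stricter or no filter (0.590 and 0.0621) and with the crossed block of unlike numbers (0.0581), in a range of 0.0369 to 0.758 over 14 alternatives. Ngp read 1.997 and S100a8 1.64 beside this group.

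**Figure D3:**
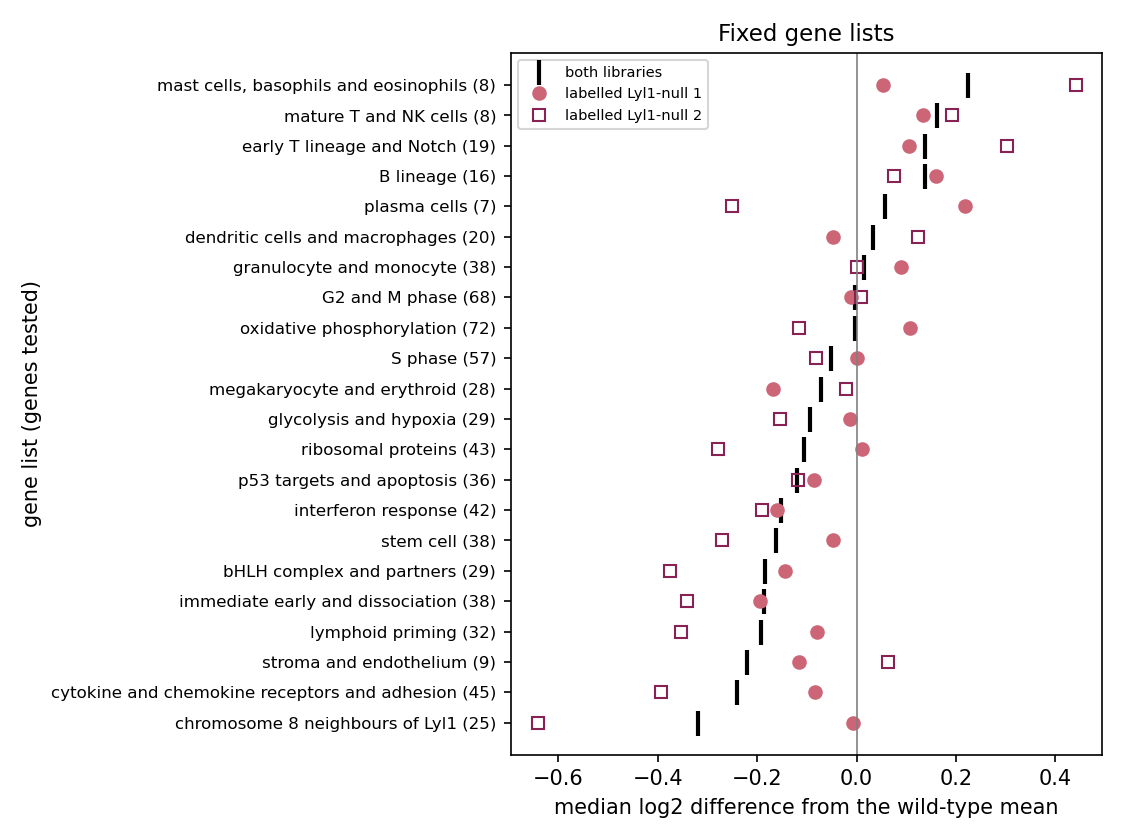
Median log2 difference from the wild-type mean (horizontal axis) of each gene list (vertical axis, number of genes tested in parentheses), with black bars for both libraries labelled Lyl1-null together, red circles for replicate 1 and open purple squares for replicate 2. The receptor and adhesion list lies at −0.24, the interferon list at −0.15 and the early T-lineage list at 0.14.

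Lymphoid priming genes went both ways. Of 32 tested members, 11 were positive and 21 negative, the list did not pass camera (adjusted p = 0.455) and 0 members passed over all genes. Without the filter it passed downward (adjusted p = 0.0298), but not with an estimated correlation there (adjusted p = 0.651). Adjusted over the list alone, 4 passed: the recombinase gene Rag2 (0.73) and Dtx4 (1.06) with higher values, and the adaptor gene Lax1 (−0.88) and Gimap6 (−0.98) with lower ones. Lax1 lies in the run of chromosome 1 genes described below. The difference was 0.29 for Rag1 (SE 0.28), −0.06 for Dntt, the terminal transferase (SE 0.17), and −0.24 for Ikzf1, which encodes Ikaros (SE 0.18), none past the threshold and each under 2 SE. The libraries labelled Lyl1-null replicate 1 and replicate 2 read −0.079 and 0.65 for Rag1, 0.052 and −0.17 for Dntt and −0.14 and −0.34 for Ikzf1. Without wild-type replicate 1 and without wild-type replicate 2, Ikzf1 was at −0.36 and −0.12, and without the latter Rag1 was at 0.15. Other probe sets above the filter read −0.25 and 0.28 for Dntt, 0.39 for Ikzf1, 0.39 for Dtx4 and −1.46 for Gimap6. In the B-lineage list, 11 of 16 genes were positive (camera adjusted p = 0.0785), 0 passed over all genes or adjusted over the list alone, and Blk read 0.71. The list passed upward without the library labelled Lyl1-null replicate 2 (adjusted p = 0.00740), without wild-type replicate 2 (0.0178) and with the mean of probe sets (0.0289). With an estimated correlation it did not pass (adjusted p = 0.758 with all libraries and 0.878 without the one labelled Lyl1-null replicate 2). Without the latter library, Ly6d (1.44), Vpreb1 (0.68) and Il7r (0.76) passed adjusted over the list alone, with Ly6d and Vpreb1 named after their values had been seen. Ngp read 1.997 beside both lists.

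The list of the transcription factor complex around Lyl1, which counts Lyl1 itself, had 21 of 29 members negative, did not pass camera (adjusted p = 0.102) and had 0 members past the threshold over all genes or adjusted over the list alone. It passed downward without the library labelled Lyl1-null replicate 2 (adjusted p = 0.0136) and without the filter (0.0225), but not with an estimated correlation there (adjusted p = 0.878 and 0.651). Leaving Lyl1 out of the list, chosen after the data had been seen, gave adjusted p = 0.161 with all libraries and 0.0940 without that one. In the latter fit 2 members passed adjusted over the list alone, Gata2 (−0.93) and Gfi1b (0.75). Without the library labelled Lyl1-null replicate 1 the list did not pass, and Gata2 read −0.70. Gata2, a factor of stem and progenitor cells, read −0.82 (SE 0.17) and Gfi1, a repressor needed for early lymphoid and neutrophil development, −0.68 (SE 0.20), at adjusted p-values of 0.574 and 0.644. Tal1 read −0.31 (SE 0.23), Lmo2 −0.11 (SE 0.21) and the E protein gene Tcf3 −0.10 (SE 0.23). Other Tcf3 probe sets above the filter read −0.70 and −0.41. The libraries labelled Lyl1-null replicate 1 and replicate 2 read −0.14 and −0.47 for Tal1, −0.32 and 0.11 for Lmo2 and 0.17 and −0.37 for Tcf3. Without wild-type replicate 1 and without wild-type replicate 2, Tal1 was at −0.55 and −0.063 and Lmo2 at −0.01 and −0.21, and without the latter Tcf3 was at −0.065. In the stem cell list, 24 of 38 genes were negative (camera adjusted p = 0.455) and 0 passed over all genes. Adjusted over that list alone, 4 passed: Ndn (−1.35), Gata2, the homeobox factor Meis1 (−0.75) and the cell cycle inhibitor Cdkn1a (1.98). Other Meis1 probe sets above the filter read −0.28 and −0.04. Cdkn1a also passed adjusted over the p53 and apoptosis list alone, where Phlda3 read 0.65. Its second probe set differed by 1.58 in the library labelled Lyl1-null replicate 1 and by −0.11 in the one labelled replicate 2.

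Granulocyte and monocyte genes went both ways, in cells sorted without lineage markers. Of 38 tested members, 20 were positive and 18 negative, the list did not pass camera (adjusted p = 0.275) and 0 passed over all genes. Adjusted over the list alone, 5 passed. The granule genes Ngp (1.997), Camp (1.84) and Ltf (1.47) and S100a8 (1.64) had higher values. Csf2rb (−1.06) had a lower one, with −0.25 in its second probe set. The primary granule genes Mpo and Ctsg read −1.01 (SE 0.30) and −0.53 (SE 0.20), neither past the threshold. Among the other cell types, mature T and NK cell genes (adjusted p = 0.455), dendritic and macrophage genes (0.533), mast cell, basophil and eosinophil genes (0.109), stroma and endothelium (0.962) and plasma cells (0.455) did not pass camera, and 0 of their members passed over all genes. The mast cell, basophil and eosinophil list passed upward with the stricter filter (adjusted p = 0.0458), but not with an estimated correlation there (adjusted p = 0.851). Its estimated correlation there, −0.991, can arise only with very few genes, so that pass rests on few members. Among the members of these lists of other cell types, the natural killer receptor gene Klrd1 (−0.76) passed adjusted over its list alone. The smallest unadjusted p-values in those lists belonged to Ccl5 (−0.68), Itgax (0.57), Cd74 (−0.37), Fcer1g (0.80), Mcpt8 (−0.80), Col4a1 (−0.48), Sparc (0.38), Fkbp11 (0.63) and Ell2 (−0.90), besides Klrd1. The libraries labelled Lyl1-null replicate 1 and replicate 2 read −0.28 and −1.09 for Ccl5, −0.26 and −0.71 for Col4a1, 0.22 and 0.54 for Sparc and −1.26 and −0.55 for Ell2.

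Megakaryocyte and erythroid genes did not pass camera (adjusted p = 0.986), with the carbonic anhydrase gene Car2 at −0.86 and the platelet chemokine gene Pf4 at −0.99. Handling-induced genes had 28 of 38 negative and a camera adjusted p of 0.0636, with Hsph1 at 0.96 and Per1 at −0.75. The list passed downward with the replicate block (adjusted p = 0.00418), quantile normalization (0.0199), no filter (0.00399) and without wild-type replicate 2 (1.45e-06), but not with an estimated correlation (adjusted p = 0.819). The S-phase list (adjusted p = 0.986, with Tyms at −0.70 and Rfc3 at −0.56) and the G2 and M list (0.760, with Cdc25b at −0.65 and Ncapd2 at −0.33) did not pass. Neither did oxidative phosphorylation (0.533, with Atp5b at −0.36 and Ndufs1 at −0.32), glycolysis and hypoxia (0.488, with Aldoc at −0.70 and Pfkm at −0.40), ribosomal proteins (0.284, with Rps27l at 0.40 and Rps4l at −0.84) or p53 targets (0.566). Megakaryocyte and erythroid genes passed downward without wild-type replicate 2 (adjusted p = 0.0132), oxidative phosphorylation upward without the library labelled Lyl1-null replicate 2 (0.00361) and ribosomal proteins downward without the one labelled replicate 1 (0.0260) and without the filter (0.0112). Camera's direction turned upward for megakaryocyte and erythroid genes without wild-type replicate 1, and for ribosomal proteins without the library labelled Lyl1-null replicate 2. It turned downward for oxidative phosphorylation without the one labelled replicate 1. The ribosomal median was 0.01 in the library labelled Lyl1-null replicate 1 and −0.28 in the one labelled replicate 2. With an estimated correlation no list passed under any of these settings (lowest adjusted p = 0.651, without the filter). Few degrees of freedom made passing unlikely there, and ribosomal proteins also had an estimated correlation of 0.667 with all libraries. The libraries labelled Lyl1-null replicate 1 and replicate 2 read −0.14 and −1.53 for Rps4l, −0.38 and −1.01 for Tyms, −0.27 and −0.84 for Rfc3, −0.31 and −0.99 for Cdc25b, −0.15 and −0.57 for Atp5b and −0.18 and −0.46 for Ndufs1. A second Tyms probe set above the filter read 0.52. Without wild-type replicate 1, Per1, Cdc25b and Tyms were at −0.50, −0.43 and −0.43. In all these lists 0 members passed over all genes with all libraries. For the G2 and M, oxidative phosphorylation and stroma lists, camera's direction was up while the list means were −0.03, −0.02 and −0.09.

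Neighbours of Lyl1 on chromosome 8 were read because a targeted allele can carry flanking sequence of another strain. Of 25 tested neighbours, 19 were negative, with a camera adjusted p of 0.0516 that missed the threshold. Gadd45gip1 (−1.57), 4 genes from Lyl1 in the order of GRCm38.p6, passed adjusted over the list alone and 0 neighbours passed over all genes, with Hook2 at −0.76. The list's adjusted p was 0.891 without the library labelled Lyl1-null replicate 2 and 0.00128 without the one labelled replicate 1, the ends of its range over 14 alternatives. With an estimated correlation it was 0.819 with all libraries and 0.832 without the one labelled replicate 1. The list also passed downward without the filter (adjusted p = 0.00215), with quantile normalization (0.00779), with the replicate block (0.00882) and without wild-type replicate 2 (0.00295), and with an estimated correlation it did not (0.651, 0.834, 0.918 and 0.792). The list median was −0.01 in the library labelled replicate 1 and −0.64 in the one labelled replicate 2.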

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

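The crossed block and the list of the Lyl1 complex without Lyl1 were added after the result had been seen. The count of 1 gene (766 at an unadjusted p under 0.05 in limma) became 4 without the filter, 2 with all probe sets, 0 with the mean of probe sets (736 at an unadjusted p under 0.05), 2 with quantile normalization, 2 with median centring, 4 with a trended prior, 5 with array weights and 6 at a threshold of 0.10. The stricter filter and the robust prior gave 1. Leaving out 1 library at a time gave 1 to 1652 genes, and Lyl1 differences of −7.17 to −1.99. Lyl1 passed without either library labelled Lyl1-null and under no other alternative. The genes called under the settings with 6 or fewer were all among the 22 found without the library labelled Lyl1-null replicate 2. Apart from fewer genes or samples tested, the cause was not tested.

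The labels share replicate numbers but do not say that a number marks a shared mouse or day. Deviations of same-numbered libraries correlated at −0.41 across genes, which are not independent replicates. With the replicate block, 3 genes passed (Ctse, Cxcr4 and Lrmda) and 5 lists. Crossed pairs gave 1 gene and 1 list, that of receptors and adhesion molecules.

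The count of 3 lists became 7 without the filter, and 2 to 6 with 1 library left out, 5 of them without the library labelled Lyl1-null replicate 2. It was 0 with fry and 3 with Lyl1 left out of the list of its complex. With an estimated correlation it was also 0, where few degrees of freedom made passing unlikely. Correlation between genes weighed on some lists as well. With all libraries it was estimated at 0.667 for ribosomal proteins, 0.400 for the neighbours of Lyl1 and 0.115 for receptors and adhesion molecules. For interferon response it was 0.0042, below the preset one.

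Of the named genes and the called lists, 1133 comparisons with an alternative kept their direction and side of the threshold, 95 newly passed, 19 no longer passed and 5 changed sign. None of those 5 passed either way. As Ctse was the only gene that passed with all libraries, most of the 1133 passed in neither fit. They do not measure how well calls held. With 1 library left out, Lmo2 ranged from −0.32 to 0.11, Rag1 from −0.079 to 0.65, Dntt from −0.17 to 0.052 and Tcf3 from −0.37 to 0.17, with the sign turned without the library labelled Lyl1-null replicate 1 for Lmo2 and without the one labelled replicate 2 for the others. Ikzf1 was 0.075 with the mean of probe sets. The cause was not tested.

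Genes near the filter of 5.69, such as Thy1 and Ltf in wild type or Lyl1 in the library labelled Lyl1-null replicate 1, have differences that background signal compresses.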

Other observations

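The tests of the chromosome 1 genes together, of Lyl1 in the library labelled Lyl1-null replicate 2 and of the correlation between probe sets were chosen after those values had been seen.

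Probe sets without a single listed gene were tested apart from the genes. Of 3671 above the filter, 0 passed in limma and 353 had an unadjusted p under 0.05.

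Several of the genes with the smallest p lie near each other on chromosome 1, away from Lyl1 on chromosome 8. Tfcp2l1, Cxcr4, Ctse and Nav1 fall within a run of 77 tested genes, and 4 of the 20 genes with the smallest p in a run of 150 tested genes exceeded the 95th percentile of 3 in 10000 random lists (permutation p = 0.0284, one-sided). Among the 22 genes found without the library labelled Lyl1-null replicate 2 there were 5, with Klhl30 (permutation p = 0.00230), but the 20 leading genes without the library labelled replicate 1 gave 3 (permutation p = 0.331). Sequence variants under the probes, which lower a signal, would not account for Nav1 and Tfcp2l1, 2 genes with fitted 95% intervals above 0. A chromosome segment that differs between the lines of mice is a candidate explanation. Of the other 73 genes of the run, 8 had an unadjusted p under 0.05, Lax1 among them. Outside the run there were 751 of 11100 (one-sided Fisher's exact p = 0.121). This leaves the segment open, as it does regulation of these genes by Lyl1, which was not tested.

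The Lyl1 signal in the library labelled Lyl1-null replicate 2 bears on every direction drawn from it. RNA of cells like those of the wild-type libraries, at the 25.1% share that Lyl1 gives, would lift the genes that fell without that library to at least that share. Of 11 such genes, 5 lay below that share, with Ctse at 6.85% of wild type, and the others above it. Set against the level predicted from that share and the library labelled replicate 1, 10 of 11 lay below (median −0.54, 95% bootstrap interval −1.05 to −0.36), with 29.3% predicted for Ctse. A swap with a wild-type library is argued against by the lowest wild-type Lyl1 value, 12.29. RNA of mice of both sexes may be present, since Xist was high while the 1 Y-linked probe set well above the filter, of Eif2s3y, stood at 31.3% of the other 3 libraries; RNA of Lyl1-expressing cells unlike the wild-type libraries stays open and was not tested.

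The same library stands apart across many genes. A narrower spread of its deposited values is argued against, because after quantile normalization its SD from the mean of the others was still 1.61 times the highest of theirs. Uneven recovery along transcripts, from RNA quality or amplification, may contribute: over 4717 genes with 2 probe sets, the disagreement within genes was 1.62 times the highest of the other libraries. That ratio rises with any wider deviation (1.56 times here), but the correlation between the probe sets of a gene was also lower, r = 0.243 against 0.308 to 0.334 (difference from the lowest −0.066, 95% bootstrap interval −0.094 to −0.029). A difference in genotype or sex of the mice remains among the open explanations and was not tested, and the array's own RNA integrity controls were not used here.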
